A study of Mus musculus with 24 samples.

How the data were processed

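Total RNA from efferent duct, epididymis and vas deferens of male CD1 mice at 3 embryonic ages (E14.5, E16.5 or E18.5) or on P1 was labelled with biotin and hybridised to Affymetrix arrays, 24 in all, with 2 for each of 12 groups of tissue and age. Per the labels, the authors extracted the RNA with Trizol and computed the values by RMA, whose version and settings are not given in the sources used here. The deposited values were found to be a ratio on a linear scale, each probe set divided by its median over the 24 arrays. For 45081 of 45101 probe sets (99.96%) the median over the 24 arrays was 1 within 1e-04. The log2 of the ratio was taken before any other step. Such values hold no level of a gene, so no signal over background can be computed from them, and the number of arrays limits the precision.

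Of the 45101 probe sets, 64 controls were left out of the gene tests, and 34945 with exactly 1 gene symbol in the probe table were used. Another 932 had several symbols and 9160 had none, and these were left out. Symbols were checked against the Entrez identifiers of the name table for the mouse assembly GRCm38.p6, where 34741 matched and 0 symbols changed. A gene was represented by 1 probe set, which gave 18193 genes, 9010 of them with several probe sets. The planned choice was the probe set with the highest mean, and the planned filter kept probe sets above the 40th percentile of an array. Both need levels and say nothing for centred ratios, so the other options set out beforehand became the main choices: the probe set with the largest variance over the arrays, and no filter. This was decided after the unit was seen and before any calls were compared. The largest variance favours probe sets that differ between arrays for any reason, including the technical differences described in the results.

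Limma 3.58.1 in R 4.3.3 was used to fit a mean per group to each gene, with contrasts and empirical Bayes moderation of the residual spread. The residual spread of a gene is shared by all 12 groups, so each SE rests on all of them and not only on the arrays compared. P-values were adjusted by the method of Benjamini and Hochberg over the 18193 genes, with a threshold of 0.05, and the count at 2-fold or more is given beside. A contrast between tissues averages the differences at the 4 ages, and a contrast between successive ages averages those of the 3 tissues. Within each tissue P1 was compared with E14.5. Moderated F tests were used for the interaction of age and tissue and for the tissue differences at each age. A gene was called enriched in a tissue when it passed and was at least 2-fold higher than in each of the other two. All tests are two-sided. The replicate numbers were not taken to pair the samples, since deviations of arrays with the same number correlated across genes at -0.22 to 0.36, with 2 of 12 pairs over 0.1.

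Gene lists, 22 of processes and 10 of cell type markers, were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The process lists covered posterior and anterior HOX genes, Wolffian duct transcription factors, steroid receptors and 5-alpha reductases, WNT, FGF and BMP with TGF-beta signalling, retinoid metabolism, planar cell polarity, motile cilia, smooth muscle, the cell cycle, interstitial matrix, basement membrane, epithelial adhesion and keratins, ion and water transport, endocytic receptors, secreted proteins of the adult epididymis, imprinted growth genes, cholesterol synthesis, antigen presentation and interferon response, and immediate early genes. The marker lists covered erythroid, endothelial, macrophage and leukocyte, Sertoli and Leydig, germ, neural and Schwann, skeletal muscle, adipocyte, kidney and mesothelial cells. Lists were tested with camera at a preset correlation of 0.01, with p-values adjusted over the 96 tests between tissues and the 96 between ages. They were also tested with an estimated correlation and with fry. The former compares a list with other genes, and fry tests whether the genes of a list move, on balance, one way.

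Genes were named by rule. For each tissue comparison these were the 10 largest called differences in each direction with the same sign at all 4 ages, and for each tissue the 10 enriched genes with the largest smaller fold. For P1 against E14.5 they were the 10 largest called changes in each direction whose arrays did not overlap between the ages, for each interval the 5 largest called, for the interaction the 10 with the smallest p, and for each list up to 5 called members by fold, or any member of lists of at most 16. Predicted genes, probe sets with no or several symbols and families with shared sequence were skipped. Array quality was read from the probe sets of the added control RNAs, of Gapdh and of Actb at their 5' and 3' ends and from the hybridisation controls.

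The settings varied by plan were quantile normalization, centring of each array on its median, the mean of all probe sets of a gene, moderation with a trend and robust to outliers, array weights, a replicate block, only the arrays of the groups compared, an estimated correlation or fry for lists, and leaving out each array. The trend in this moderation follows the mean log2 ratio, not the intensity. Chosen after seeing the data were the fits without 4 late vas deferens arrays, without 4 early efferent duct arrays and without both, the probe set with the highest mean, the probe set by variance over the other 20 arrays, and the genes above the median variance. The highest mean of centred ratios is not the highest level. It favours a probe set that does not fall in a few arrays over one that does, so a smaller fall is partly fixed by this choice. The fit was tested on simulated data, in which 200 of 18193 genes were given a known change. For efferent duct against epididymis 88.1% of those changed by 0.5 (log2) were recovered and 100% of those changed by 1, with 10 false calls. For P1 against E14.5 in the epididymis 23.9% of changes of 0.5, 74.6% of 1 and 97.0% of 2 were recovered, with 9 false calls. The simulated noise was normal and independent between genes, with the same SD in all arrays for a gene and no differences between arrays. The real arrays have unequal spreads and technical differences, so the simulation does not measure the false calls among the real ones. Figures were drawn with matplotlib. Probe intensities were not used here.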

Results

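Gene expression was measured on 24 Affymetrix arrays of total RNA from 3 segments of the excurrent duct of male CD1 mice. These were the efferent duct, which carries fluid from the testis, the epididymis, in which sperm mature in the adult, and the vas deferens. Each segment was sampled at embryonic days 14.5, 16.5 and 18.5, written as E14.5 and so on, and on postnatal day 1 (P1), with 2 arrays in each of the 12 groups. The series compares the segments with each other and follows each of them through development. A value is the log2 ratio of a probe set to its median over the 24 arrays, so it tells how arrays differ for a gene and not how abundant the gene is. The number of arrays limits the precision. P-values measure only the spread between these samples, since the labels do not say whether each array holds a separate animal or a pool.

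The leading 4 principal components of 18193 genes held 40.6%, 18.2%, 17.7% and 5.1% of the variance. The 4 vas deferens arrays of E18.5 and P1 lay at 75.25 to 77.65 on the first component and the other 20 arrays at -43.29 to 17.93, and the 4 efferent duct arrays of E14.5 and E16.5 lay at 38.13 to 56.1 on the second and the other 20 at -28.41 to 18.28. Both sets also stood apart in control probe sets. In the 4 vas deferens arrays of E18.5 and P1, called late vas deferens arrays here, the 5' minus 3' log2 difference of control RNAs added to the sample was -1.46 to -1.16, against -1.02 to 0.55 in the other 20 arrays. The same difference for Gapdh was -2.94 to -2.68 in these 4 arrays and -0.54 to 0.19 in the others. In the 4 efferent duct arrays of E14.5 and E16.5, called early efferent duct arrays, the hybridisation controls were at -1.31 to -0.40 (log2), against -0.39 to 0.35 elsewhere. The interquartile range of the log2 ratios was 0.48 to 0.61 in these 4 arrays and 0.18 to 0.43 in the others. Replicates correlated across probe sets with r = 0.407 in the epididymis at E14.5 and 0.712 to 0.929 in the other groups. Probe sets are not independent replicates. Several counts and values are therefore also given without these sets of 4 arrays. Leaving out either set also leaves out 2 ages of a tissue comparison, and a tissue from some averages over tissues.

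**Figure D1:**
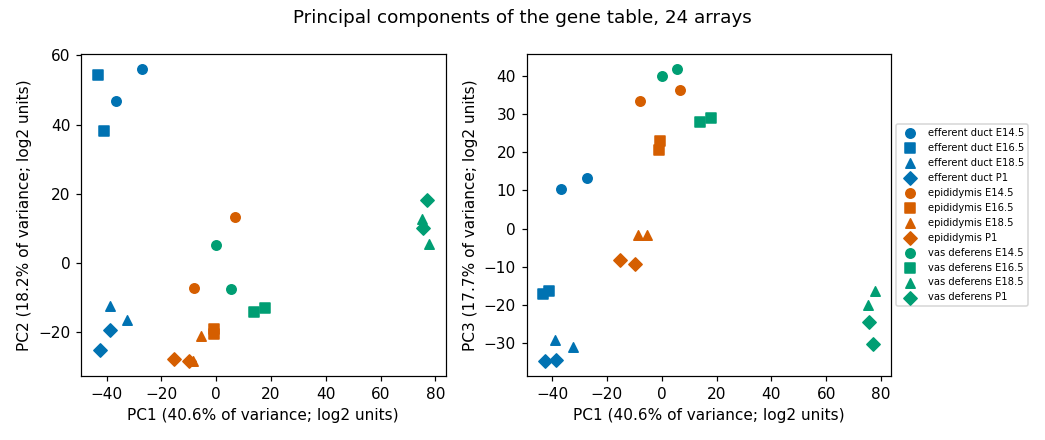
Scores of the 24 arrays (log2 units) on the first principal component (x axes) and on the second (left) or the third (right), which hold 40.6%, 18.2% and 17.7% of the variance of 18193 genes. Each point is an array, colour stands for tissue and marker shape for age, and the 4 vas deferens arrays of E18.5 and P1 lie at 75.25 to 77.65 on the first component.

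**Figure D2:**
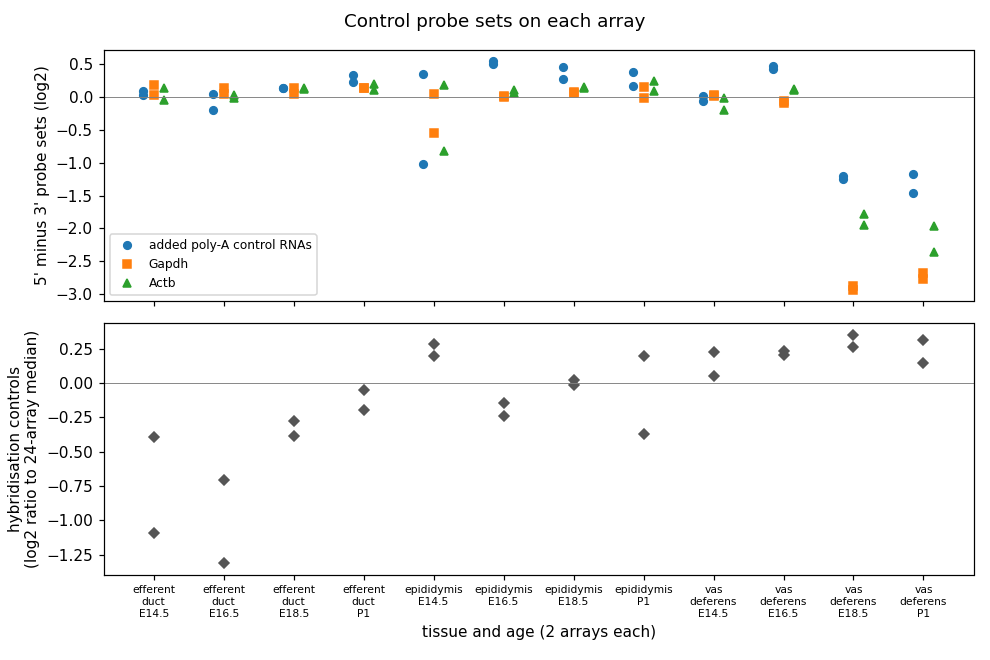
Per array, the 5' minus 3' log2 difference of the added control RNAs, Gapdh and Actb (top) and the log2 ratio of the hybridisation controls (bottom), for the 24 arrays by tissue and age. The added control RNAs lie at -1.46 to -1.16 in the 4 late vas deferens arrays, and the hybridisation controls at -1.31 to -0.40 in the 4 early efferent duct arrays.

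The comparison of efferent duct with epididymis asks which genes set neighbouring segments apart before and just after birth. Genes of ion and water transport, endocytic receptors and antigen presentation were higher in the efferent duct, and posterior HOX genes and smooth muscle genes were lower. Pdzk1, a scaffold of apical transporters, was 20.4-fold higher in the efferent duct (log2 4.35 ± 0.12 SE, 8 arrays per tissue, adjusted p = 2.07e-14). Cldn2, a claudin that forms cation and water pores in tight junctions, was 15.5-fold higher (log2 3.95 ± 0.11), and Slc26a3, a chloride and bicarbonate exchanger, 12.3-fold higher (3.62 ± 0.12). Cldn8, a claudin of barrier type, was 28.3-fold lower (log2 -4.82 ± 0.08, adjusted p = 2.81e-17). Hoxc10, a transcription factor of posterior body patterning, was 16.4-fold lower (log2 -4.03 ± 0.07).

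The further genes named were taken from those with the same sign at all 4 ages. Beside Pdzk1, Cldn2 and Slc26a3, those higher in the efferent duct were Keg1 (14.2-fold), Vil1, an actin bundler of microvilli (9.46-fold), Fxyd2, a regulator of the sodium pump (7.87-fold), Aldh1l1, a folate enzyme (7.85-fold), Ptgds, a prostaglandin D synthase (7.23-fold), Unc5cl (7.20-fold) and Clrn3 (7.17-fold). Those lower were Rprm, a gene of cell cycle arrest (14.5-fold), Spink8, a predicted protease inhibitor (13.8-fold), Hoxd10 (11-fold), Hoxa10 (8.94-fold), Irs4, an adaptor of insulin signalling (8.90-fold), Myocd, a coactivator of smooth muscle genes (8.64-fold), Vstm2a (8.40-fold) and Osr2, a zinc finger transcription factor (8.18-fold). The other probe set of Hoxa10 gave a log2 difference of 0.08, and that of Irs4 also gave 0.08. That of Myocd gave -0.37, that of Osr2 -0.36 and the medians for Aldh1l1, Cldn2 and Fxyd2 were 0.29, 2.17 and 1.85.

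By fixed list, 23 of 34 genes of ion and water transport were higher in the efferent duct, 2 were lower and 9 did not pass (adjusted p = 4.9e-08 for the list, and adjusted p = 0.00875 with an estimated correlation). Besides Slc26a3 these included Aqp1, a water channel (3.67-fold), Car2, a carbonic anhydrase (3.55-fold), and Cftr, a chloride channel (3.32-fold). Of 12 endocytic receptors and partners, 8 were higher, 1 was lower and 3 did not pass (adjusted p = 0.00183, and adjusted p = 0.0342 with an estimated correlation). Lrp2, which encodes megalin, was 6.36-fold higher, Folr1, a folate receptor, 4.98-fold higher, and Vldlr 3.0-fold lower. Counts for lists are adjusted over all genes tested, and those adjusted over the list alone were the same unless they stand beside them. In the list of antigen presentation and interferon response, 17 of 20 genes were higher and 1 was lower (18 and 1 adjusted over the list alone; adjusted p = 2.53e-07, and adjusted p = 0.00875 with an estimated correlation), with H2-Ab1 (3.33-fold) and Cd74 (3.17-fold) of class II presentation among them. Macrophage and leukocyte markers were higher for 17 of 18 genes, such as Ctss (2.0-fold) and C1qb (1.96-fold), with adjusted p = 4.9e-08 and adjusted p = 0.102 with an estimated correlation. Cd74, H2-Aa and H2-Ab1 are also made by macrophages.

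Among the lists lower in the efferent duct, 8 of 14 posterior HOX genes were lower, 3 were higher and 3 did not pass (adjusted p = 0.000882, and adjusted p = 0.0256 with an estimated correlation). Of 20 smooth muscle genes, 12 were lower, 2 were higher and 6 did not pass (adjusted p = 0.00183, and adjusted p = 0.0496 with an estimated correlation). Myh11, smooth muscle myosin, was 3.58-fold lower and Actg2, an enteric type actin, 2.62-fold lower. Cell cycle genes were lower for 19 of 29 members and higher for 0 (21 lower adjusted over the list alone), each by less than 2-fold, as for Cenpe (1.61-fold) and Top2a (1.52-fold), with adjusted p = 0.000409 and adjusted p = 0.177 with an estimated correlation. WNT signalling genes were lower for 16 of 35 and higher for 5, with Wnt5a 5.23-fold and Wnt6 2.80-fold lower (adjusted p = 0.0437, and adjusted p = 0.14 with an estimated correlation). Without the early efferent duct arrays the WNT list had adjusted p = 0.088 and a median of -0.03 (log2), against -0.17 on all arrays. Its call was also lost with a replicate block. Endothelial markers were lower for 9 of 16 and higher for 0, with Sox17 2.45-fold lower (adjusted p = 0.0121, and adjusted p = 0.291 with an estimated correlation).

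Further lists were called higher in the efferent duct with the preset correlation, but not with an estimated correlation. Epithelial adhesion genes and keratins were higher for 14 of 28 and lower for 5, such as Cldn7 (1.79-fold) and Krt7 (1.79-fold), with adjusted p = 0.048 and adjusted p = 0.39 with an estimated correlation. This call was lost with a replicate block. The remaining calls rested on the early efferent duct arrays, in which the hybridisation controls were low. Secreted proteins of the adult epididymis were higher for 7 of 24 and lower for 1 (adjusted p = 0.0279, adjusted p = 0.222 with an estimated correlation, and adjusted p = 0.59 without these arrays). Ptgds and Gpx3, a secreted glutathione peroxidase (2.10-fold), led that list. Sertoli and Leydig markers, which also hold Ptgds, were higher for 5 of 13 and lower for 1 (adjusted p = 0.0262, adjusted p = 0.153 with an estimated correlation, and adjusted p = 0.065 without these arrays), with Sox9 2.41-fold and Cyp11a1, a steroid side chain cleavage enzyme, 2.0-fold higher. Germ cell markers were higher for 5 of 12 and lower for 0, led by Dazl (1.49-fold), with adjusted p = 0.0392, adjusted p = 0.124 with an estimated correlation and adjusted p = 0.83 without these arrays. Kidney markers were higher for 7 of 13 and lower for 1 (adjusted p = 0.0308, adjusted p = 0.153 with an estimated correlation, and adjusted p = 0.81 without these arrays), led by Umod (1.52-fold), with Aqp2 also in the transport list. Adipocyte markers were higher for 6 of 10 and lower for 0, led by Fabp4 (2.62-fold), with adjusted p = 0.0161, adjusted p = 0.153 with an estimated correlation and adjusted p = 0.14 without these arrays.

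In lists with no call in any comparison on all arrays, single members still differed between these segments. Of 11 Wolffian duct transcription factors, 3 were higher in the efferent duct and 5 lower (adjusted p = 0.211), with Gata3 5.91-fold lower. Without the late vas deferens arrays camera called this list lower than in the vas deferens, in the epididymis (adjusted p = 0.024) and the efferent duct (adjusted p = 0.013). Without both sets the former had adjusted p = 0.054. Of 10 steroid receptors and 5-alpha reductases, 5 were higher and 1, the oestrogen receptor gene Esr1 (log2 -0.77), was lower (adjusted p = 0.379). BMP and TGF-beta signalling had 7 higher and 13 lower of 29 (adjusted p = 0.367), with Bmp2 at -1.89 and Inhbb at 1.27 (log2). Planar cell polarity genes had 5 higher and 8 lower of 20 (adjusted p = 0.4), and motile cilium genes 17 higher and 5 lower of 32 (adjusted p = 0.0573). Neural and Schwann markers had 9 higher and 3 lower of 17 (adjusted p = 0.185), and skeletal muscle markers 6 higher and 2 lower of 16 (adjusted p = 0.298). In all, 10386 of 18193 genes passed adjusted p under 0.05, 4893 of them higher in the efferent duct and 5493 lower, with 223 and 296 at 2-fold or more. This balance turned with the scaling, to 4861 higher and 4316 lower after quantile normalization and 5468 and 5147 after array median centring. Without the early efferent duct arrays the count was 3995, of which 2271 were higher and 1724 lower, with 363 and 245 at 2-fold or more.

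HOX genes led the single genes named between epididymis and vas deferens. Hoxc8 was 17.9-fold higher in the epididymis (log2 4.16 ± 0.19 SE, 8 arrays per tissue, adjusted p = 1.04e-11) and 3.94 on the log2 scale without the late vas deferens arrays. Hoxd13, which patterns the most posterior structures, was 21.5-fold lower in the epididymis (log2 -4.43 ± 0.09, adjusted p = 2.85e-16) and -3.71 without those arrays, where Nts was at -3.89. As lists, smooth muscle genes (adjusted p = 0.0224 with an estimated correlation), anterior HOX genes (0.0521) and macrophage markers (0.163) were higher in the epididymis, and posterior HOX (0.124) and endothelial genes (0.153) were lower, so of these calls the smooth muscle one alone held with an estimated correlation. The median of the smooth muscle list, however, went from 0.60 to 0.08 (log2) without the late vas deferens arrays.

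Higher in the epididymis, among genes chosen for the same sign at all 4 ages, were Foxl2os, an antisense transcript at Foxl2 (8.30-fold), Lcn2, a secreted carrier of siderophores (7.18-fold), Hoxc6 (6.41-fold), Adamts16, a matrix protease (5.85-fold), Cnmd, a cartilage glycoprotein (4.96-fold), Hoxc5 (4.78-fold) and Arhgap20 (4.67-fold). Lcn2 had a log2 difference of 2.84 ± 0.18, and 1.25 without the late vas deferens arrays. S100a10 and Lrrc17 were both 4.85-fold higher by their main probe sets, but S100a10 was at 0.29 (log2) without the late vas deferens arrays. The other probe sets of S100a10 gave a median of -0.06, that of Lrrc17 gave -0.07 and that of Adamts16 gave 0.17 (adjusted p = 0.11), and the probe sets of Hoxc6 and Hoxc5 with the highest mean gave 0.39 and 0.90. Lower in the epididymis were Eya1, a coactivator with phosphatase activity (8.45-fold), Nts, the neurotensin precursor (7.40-fold), Slc26a7, an anion exchanger (7.32-fold), Pcdh10, a protocadherin (6.71-fold), Cxxc4 (6.45-fold), Kcnd2, a potassium channel (6.14-fold), Elavl2, an RNA binding protein (5.96-fold), Dach2 (5.85-fold) and Rmdn2 (5.77-fold). Without the late vas deferens arrays Eya1 was at -1.65 (log2), Pcdh10 at -1.50, Kcnd2 at -1.61 and Dach2 at -1.66. The median of the other probe sets was -1.29 for Hoxd13, -1.0 for Eya1, -0.41 for Slc26a7, -1.07 for Pcdh10, -1.17 for Cxxc4, -0.99 for Kcnd2 and -0.87 for Elavl2.

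Anterior HOX genes were higher in the epididymis for 15 of 19 members and lower for 0 (adjusted p = 4.29e-07, and adjusted p = 0.0521 with an estimated correlation). Posterior HOX genes were lower for 7 of 14 and higher for 3, with Hoxa11 5.40-fold lower and Hoxc9 3.55-fold higher (adjusted p = 0.0437, adjusted p = 0.124 with an estimated correlation, and adjusted p = 0.16 by the probe sets with the highest mean). Of 20 smooth muscle genes, 13 were higher and 2 lower (14 and 2 adjusted over the list alone; adjusted p = 9.55e-05, and adjusted p = 0.0224 with an estimated correlation). Myh11 was 4.09-fold, Tagln 2.49-fold and Cnn1, calponin, 2.25-fold higher, with 0.02 (log2) for the median of the other probe sets of Myh11, and the list median went from 0.60 to 0.08 (log2) without the late vas deferens arrays, with the call kept (adjusted p = 0.00036). Retinoid genes were higher for 8 of 16 and lower for 0, with Crabp1 3.20-fold and Crabp2 2.16-fold higher, both carriers of retinoic acid (adjusted p = 0.0161, and adjusted p = 0.0836 with an estimated correlation). Imprinted growth genes were higher for 13 of 18 and lower for 2, among them Dlk1 (3.01-fold) and Peg3 (2.98-fold), with adjusted p = 0.00125 and adjusted p = 0.124 with an estimated correlation. That list's median went from 0.62 to 0.23 (log2) without the late vas deferens arrays.

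Interstitial matrix genes were higher in the epididymis for 14 of 24 and lower for 1 (14 and 3 adjusted over the list alone), such as Ogn (2.65-fold) and Postn (2.49-fold), with adjusted p = 0.00186 and adjusted p = 0.381 with an estimated correlation. Basement membrane genes were higher for 14 of 21 and lower for 5, with Nid1 2.90-fold and Col4a6 2.43-fold higher (adjusted p = 0.0164, and adjusted p = 0.222 with an estimated correlation). Their median went from 0.46 to 0.12 (log2) without the late vas deferens arrays, and the list had adjusted p = 0.059 without both sets. Epithelial adhesion genes and keratins had 16 higher and 5 lower of 28 (17 and 5 adjusted over the list alone), with Cldn3 1.92-fold higher (adjusted p = 0.0072, and adjusted p = 0.225 with an estimated correlation). With the late vas deferens arrays left out, that list's median was -0.02 and its adjusted p = 0.53. Macrophage markers were higher for 13 of 18 and lower for 0 (14 and 0 adjusted over the list alone), with the complement genes C1qb 3.88-fold and C1qa 2.84-fold higher (adjusted p = 1.48e-05, and adjusted p = 0.163 with an estimated correlation). Mesothelial markers were higher for 6 of 11 and lower for 1, led by Rspo1 (2.41-fold), which the WNT list also holds (adjusted p = 0.0308, and adjusted p = 0.332 with an estimated correlation). Endothelial markers were lower for 9 of 16 and higher for 1, with Sox17 2.57-fold and Erg 2.18-fold lower (adjusted p = 0.000455, and adjusted p = 0.153 with an estimated correlation). In total 8089 genes passed, 4401 higher in the epididymis and 3688 lower, with 479 and 176 at 2-fold or more. Without the late vas deferens arrays 1050 passed, 525 in each direction, with 82 and 72 at 2-fold or more.

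The ends of the duct, efferent duct and vas deferens, differed on all arrays in more genes than either neighbouring pair, at 12644, of which 7054 were higher in the efferent duct and 5590 lower (864 and 908 at 2-fold or more). Each age of this comparison holds early efferent duct or late vas deferens arrays, so it has no value without both sets. Technical and tissue differences therefore cannot be told apart in this count. Cldn2 was 30.3-fold higher in the efferent duct (log2 4.92 ± 0.11 SE, 8 arrays per tissue, adjusted p = 4.03e-16) and Pdzk1 24.5-fold higher (log2 4.61 ± 0.12). Hoxd10 was 41.3-fold lower in the efferent duct (log2 -5.37 ± 0.09, adjusted p = 1.28e-17), and Hoxa10 32.7-fold lower (log2 -5.03 ± 0.18), though its other probe set gave -1.0. Keg1 (16.8-fold), Slc26a3 (15.9-fold), Lcn2 (14.7-fold), Ptgds (13.5-fold), Epyc, a small proteoglycan (11.6-fold), Vil1 (10.9-fold), Fxyd2 (10.7-fold) and Defb19, a beta-defensin (10.6-fold), followed among genes higher in the efferent duct. Cldn8 (23.7-fold), Kcnd2 (21.3-fold), Hoxd13 (log2 -4.32), Cxxc4 (19.4-fold), Elavl2 (17.4-fold), Pde7b, a cyclic AMP phosphodiesterase (15.2-fold), Hoxa11 (15.1-fold) and Rprm (13-fold) followed among those lower. With the late vas deferens arrays left out, Cldn2 was at 3.69 (log2), Keg1 at 3.11, Lcn2 at 2.48, Ptgds at 2.35, Vil1 at 2.56, Fxyd2 at 2.77, Kcnd2 at -3.46, Hoxd13 at -3.42 and Cxxc4 at -3.29. Without the early efferent duct arrays they were, in this order, at 6.15, 5.04, 5.27, 5.16, 4.33, 4.09, -5.36, -5.23 and -5.26. The median of the other probe sets was 2.31 for Cldn2, 2.07 for Fxyd2, -1.41 for Kcnd2, -1.35 for Hoxd13, -1.69 for Cxxc4, -0.81 for Elavl2 and -0.95 for Pde7b.

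Between these ends, anterior HOX genes were higher in the efferent duct for 17 of 19 and lower for 1, with Hoxc5 6.55-fold and Hoxa5 4.53-fold higher (adjusted p = 3e-05, and adjusted p = 0.102 with an estimated correlation). Posterior HOX genes were lower for 9 of 14 and higher for 1 (adjusted p = 0.000172, and adjusted p = 0.0163 with an estimated correlation). Ion and water transport genes were higher for 26 of 34 and lower for 2 (26 and 3 adjusted over the list alone), with Aqp1 6.36-fold higher (adjusted p = 0.000178, and adjusted p = 0.0342 with an estimated correlation). Endocytic receptors were higher for 10 of 12 and lower for 2, with Folr1 8.50-fold higher, Lrp2 5.88-fold higher and Vldlr 6.14-fold lower (adjusted p = 0.0019, and adjusted p = 0.0342 with an estimated correlation). Antigen presentation genes were higher for 18 of 20 and lower for 0, with B2m 4.18-fold higher (adjusted p = 1.22e-05, and adjusted p = 0.0163 with an estimated correlation). Macrophage markers were higher for 17 of 18 and lower for 0, C1qb by 7.61-fold (adjusted p = 2.88e-07, and adjusted p = 0.124 with an estimated correlation).

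WNT genes had 7 higher and 17 lower of 35, with Sfrp1, a WNT antagonist, 7.65-fold higher in the efferent duct and Rspo3, a WNT enhancer, 4.02-fold lower (adjusted p = 0.0164, adjusted p = 0.102 with an estimated correlation, and adjusted p = 0.088 without the early efferent duct arrays). The WNT list median did not shrink without the early efferent duct arrays, at -0.25 (log2) against -0.16 on all arrays. Matrix genes had 16 higher and 4 lower of 24, led by Ogn (4.26-fold), with adjusted p = 0.01, adjusted p = 0.454 with an estimated correlation and adjusted p = 0.1 without the early efferent duct arrays. Their median was 0.49 (log2) on all arrays and 0.42 without the early efferent duct arrays. Imprinted growth genes had 13 higher and 2 lower of 18 (15 and 2 adjusted over the list alone), with Plagl1 4.0-fold higher (adjusted p = 0.01, adjusted p = 0.19 with an estimated correlation, and adjusted p = 0.14 without the late vas deferens arrays). The median of these imprinted genes was 0.44 (log2) on all arrays and 0.38 without the late vas deferens arrays. Epithelial genes had 19 higher and 7 lower of 28, with Krt7 3.13-fold higher (adjusted p = 0.0188, and adjusted p = 0.302 with an estimated correlation). That list's median was -0.09 and its adjusted p = 0.98 without the late vas deferens arrays. Endothelial markers had 1 higher and 12 lower of 16 (1 and 13 adjusted over the list alone), Sox17 by 6.30-fold and Erg by 3.36-fold (adjusted p = 0.000108, and adjusted p = 0.124 with an estimated correlation). The count of genes was 11978 without the late vas deferens arrays, and its balance turned, with 5283 higher in the efferent duct and 6695 lower (527 and 1173 at 2-fold or more). It was 10608 without the early efferent duct arrays, with 5612 higher and 4996 lower (2501 and 1139 at 2-fold or more).

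Genes at least 2-fold higher in a tissue than in each of the other two numbered 204 for the efferent duct, 33 for the epididymis and 157 for the vas deferens. The efferent duct set was led by genes already named, Pdzk1 to Clrn3, of which Aldh1l1 was 8.03-fold, Unc5cl 7.93-fold and Clrn3 7.14-fold higher than in the vas deferens. In the epididymis Foxl2os was 5.04-fold higher than in the efferent duct and 8.30-fold higher than in the vas deferens. Irs4 (8.90-fold and 4.09-fold), Brinp3 (4.19-fold and 3.68-fold), Myh11 (3.58-fold and 4.09-fold), Hoxc9 (3.33-fold and 3.55-fold), Crabp1 (3.73-fold and 3.20-fold), Hoxc8 (3.12-fold and 17.9-fold), Foxl2, a forkhead factor best known from the ovary (2.89-fold and 3.52-fold), Wfdc1 (2.88-fold and 4.38-fold) and Spink12, a protease inhibitor (3.06-fold and 2.73-fold), followed, in the same order of tissues. The other probe set of Foxl2 was at 0.07 (log2) in efferent duct against epididymis, and those of Irs4 and Myh11 were at 0.20 and 0.02 in epididymis against vas deferens. With the late vas deferens arrays left out, Spink12 (0.37), Wfdc1 (0.94) and Crabp1 (0.97) were less than 2-fold higher in the epididymis than in the vas deferens. In the vas deferens Hoxd13 was 21.5-fold higher than in the epididymis, and efferent duct minus vas deferens was -4.32 (log2). Eya1 was higher by 8.45-fold and 9.52-fold, Slc26a7 by 7.32-fold and 7.03-fold, and Hoxa11 by 5.40-fold and 15.1-fold. Without the late vas deferens arrays the 3 counts were 141, 23 and 64, and without the early efferent duct arrays 322, 38 and 163. With whole groups exchanged between tissues, 4, 26 and 6 of 100 splits, the real one included, gave as many genes. The counts for epididymis and vas deferens also moved with the normalization or the choice of probe set, as stated below.

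Tissue differences were present at every age, and several grew after E14.5. Lrp2 exceeded its epididymal level by 1.00 (log2, 2 arrays per group, adjusted p = 0.000305) in the efferent duct at E14.5, by 3.06 at E16.5 and by 3.32 at P1. Aqp1 differed by 0.29 at E14.5 (adjusted p = 0.08) and by 2.0, 2.31 and 2.90 at the later ages. Hoxc10 and Cldn8 already differed at E14.5, by -3.85 and -4.13. Eya1 was at -0.80 in epididymis against vas deferens at E14.5 and at -2.50, -4.25 and -4.77 at E16.5, E18.5 and P1. Fst, an activin antagonist, went from 0.28 (adjusted p = 0.766) at E14.5 and -0.13 (adjusted p = 0.97) at E16.5 to -4.29 at E18.5 and -4.74 at P1, the ages of the late vas deferens arrays. An F test over the 3 tissues passed 9007 genes at E14.5, 10214 at E16.5, 8658 at E18.5 and 9051 at P1.

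**Figure D3:**
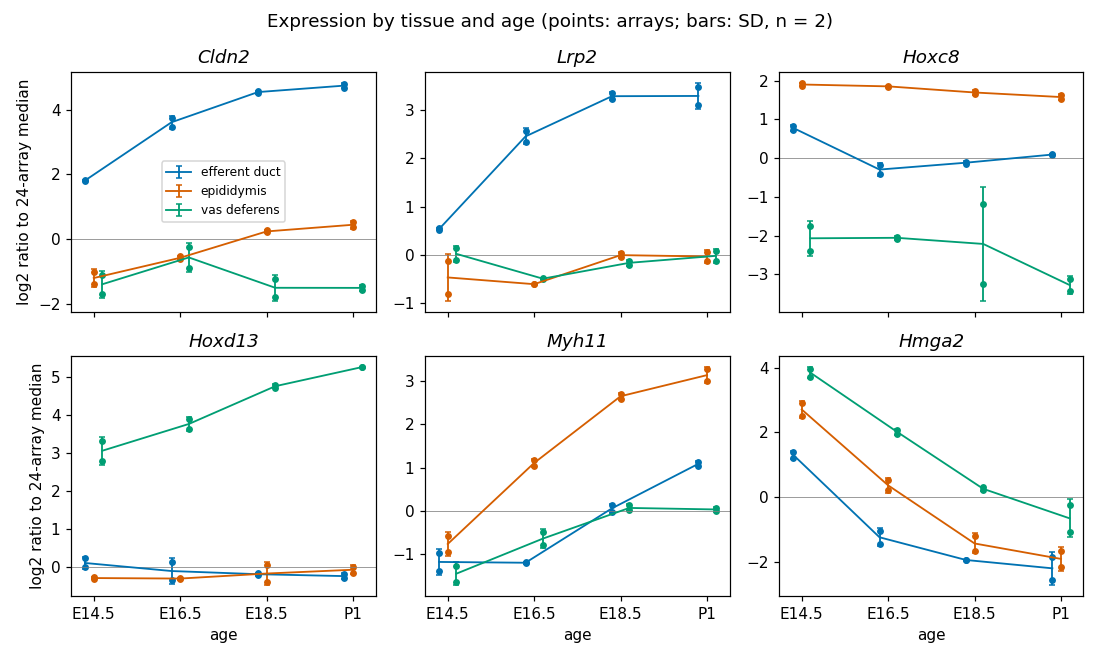
Log2 ratio to the 24-array median (y axis) of Cldn2, Lrp2, Hoxc8, Hoxd13, Myh11 and Hmga2 at the 4 ages (x axis) in each tissue, as the mean ± SD of 2 arrays with the arrays as points. Lrp2 rose by 2.76 from E14.5 to P1 in the efferent duct, Myh11 rose by 3.91 in the epididymis, and Hmga2 fell by 4.50 in the vas deferens.

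From E14.5 to P1 matrix (adjusted p = 0.331 with an estimated correlation), epithelial (0.0675) and endocytic receptor genes (0.0578) rose in the efferent duct as lists, and erythroid genes fell (0.0274), the last of these the one call that held with an estimated correlation. Lcn2 rose 47.1-fold (log2 5.56 ± 0.36 SE, 2 arrays per age, adjusted p = 2.11e-09) and Dpt, a matrix protein of connective tissue, 32.3-fold (log2 5.01 ± 0.22). Hbb-y, an embryonic globin, fell 541-fold (log2 -9.08 ± 0.38), and Hmga2, a chromatin protein of fetal growth, 11.4-fold (log2 -3.51 ± 0.26). After quantile normalization the log2 changes were 4.15 for Lcn2, 3.73 for Dpt, -7.14 for Hbb-y and -3.51 for Hmga2. This step gives the log2 ratios of all arrays the same spread, so large ratios shrink or grow by it. Sult1e1, an oestrogen sulfotransferase (33.0-fold), Cp, ceruloplasmin (31.2-fold), Mfap5, a microfibril protein (29.4-fold), Col4a4, a basement membrane collagen (27.5-fold), Aspn, a small proteoglycan (24.9-fold), Abca8a, a transporter (21.5-fold), Ehf, an epithelial transcription factor (20.8-fold), and Fndc1 (20.4-fold) also rose. The other probe set of Fndc1 gave -0.05, the median for Ehf was 1.83, and the probe set of Col4a4 with the highest mean gave 2.05. Hba-x (16-fold), Adam6b (10.9-fold), Top3b (9.84-fold), Ndnf (9.56-fold), Dnajc21 (9.07-fold), Ddx5 (8.45-fold), Kalrn (8.19-fold) and Aldh2 (7.10-fold) fell. For Top3b, Ddx5, Aldh2, Ndnf, Dnajc21 and Kalrn the median of the other probe sets was 0.23, 0.29, 0.10, -0.09, -0.15 and -0.53, and the E14.5 arrays of this comparison are among the early efferent duct arrays.

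Epithelial adhesion genes and keratins rose for 21 of 28 and fell for 1 in the efferent duct (22 and 1 adjusted over the list alone; adjusted p = 4.59e-06, and adjusted p = 0.0675 with an estimated correlation). Esrp1, an epithelial splicing factor, rose 8.62-fold and Epcam 3.97-fold. Endocytic receptors rose for 8 of 12 and fell for 0, with Lrp2 up 6.76-fold (adjusted p = 0.00431, and adjusted p = 0.0578 with an estimated correlation). Matrix genes rose for 17 of 24 and fell for 0 (18 and 0 adjusted over the list alone), with Eln, elastin, up 5.09-fold (adjusted p = 0.000363, and adjusted p = 0.331 with an estimated correlation). FGF signalling genes rose for 14 of 23 and fell for 0, with Fgf1 up 4.37-fold and the feedback inhibitor Spry4 3.54-fold (adjusted p = 0.00748, adjusted p = 0.097 with an estimated correlation, and adjusted p = 0.17 by the probe sets with the highest mean). Antigen presentation genes rose for 14 of 20 and fell for 1, H2-Aa by 5.84-fold (adjusted p = 0.0013, and adjusted p = 0.0578 with an estimated correlation), and macrophage markers rose for 11 of 18 and fell for 0, Cd14 by 2.33-fold (adjusted p = 0.0197, and adjusted p = 0.554 with an estimated correlation). Mesothelial markers rose for 9 of 11 and fell for 1, with Msln up 7.57-fold and Gpm6a 6.31-fold (adjusted p = 0.000752, and adjusted p = 0.149 with an estimated correlation).

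Posterior HOX genes fell in the efferent duct for 9 of 14 and rose for 1, Hoxd11 by 2.31-fold (adjusted p = 0.00523, and adjusted p = 0.0578 with an estimated correlation). Erythroid markers fell for 9 of 13 and rose for 0 (adjusted p = 3.35e-05, and adjusted p = 0.0274 with an estimated correlation). Endothelial markers fell for 7 of 16 and rose for 0, Emcn by 2.30-fold (adjusted p = 0.00523, and adjusted p = 0.266 with an estimated correlation). Germ cell markers fell for 6 of 12 and rose for 0, Dppa3 by 2.22-fold (adjusted p = 0.00748, and adjusted p = 0.0635 with an estimated correlation). Among Wolffian duct factors Lhx1 rose 9.86-fold. In all 8940 genes passed, 5506 up and 3434 down (1574 and 444 at 2-fold or more), against 2894 up and 2891 down after quantile normalization. This comparison has no value without the early efferent duct arrays.

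In the epididymis the change from E14.5 to P1 was led by smooth muscle genes (adjusted p = 0.000562 with an estimated correlation) and by matrix genes, whose call was lost with an estimated correlation (adjusted p = 0.0578). Aspn rose 51.5-fold (log2 5.69 ± 0.38 SE, 2 arrays per age, adjusted p = 5.91e-09), Lcn2 57.0-fold (log2 5.83 ± 0.36) and Aldh1a1, a retinaldehyde dehydrogenase, 47.9-fold (log2 5.58 ± 0.26). The SE comes from a spread shared by all 12 groups. Across probe sets, the replicate difference had an SD of 0.393 in the epididymis at E14.5 and 0.143 to 0.345 in the other groups, so the SE may be too small here. Myh11 rose 15.0-fold (log2 3.91 ± 0.16) and Actg2 12.4-fold (3.64 ± 0.28). Hbb-y fell 668-fold (log2 -9.38 ± 0.38) and Hmga2 24.5-fold (log2 -4.62 ± 0.26). After quantile normalization Hbb-y was at -8.28 and Hmga2 at -6.78. Defb29, a beta-defensin (35.6-fold), Dpt (22.6-fold), B4galnt2, a glycosyltransferase (21.2-fold), Maob, a monoamine oxidase (20.2-fold), Pdlim3, a protein of muscle Z discs (19-fold), Aldh1a7 (15.5-fold) and Lox, which crosslinks collagen and elastin (15.3-fold), rose. The fallers were Hba-x (30.9-fold), Amhr2, the receptor of anti-Müllerian hormone (12.5-fold), Wif1, a WNT inhibitor (8.64-fold), Ndnf (8.56-fold), Hand2, a mesenchymal transcription factor (7.92-fold), Hbb-bh1 (6.97-fold), St8sia1 (6.76-fold) and Ntsr1, a neurotensin receptor (6.26-fold). The probe set of Lox with the highest mean was at 0.36 (adjusted p = 0.11), and the median of the other probe sets was 1.68 for Lox, 1.71 for B4galnt2, -0.15 for Ndnf, -0.94 for Hand2 and -0.56 for St8sia1.

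Smooth muscle genes rose in the epididymis for 11 of 20 and fell for 0 (13 and 0 adjusted over the list alone; adjusted p = 4.44e-14, and adjusted p = 0.000562 with an estimated correlation). Interstitial matrix genes rose for 20 of 24 and fell for 0 (20 and 1 adjusted over the list alone), with Mfap5 up 14.4-fold and Ogn 13.2-fold (adjusted p = 5.06e-17, and adjusted p = 0.0578 with an estimated correlation). Epithelial genes rose for 12 of 28 and fell for 1 (15 and 1 adjusted over the list alone), with Esrp1 up 2.94-fold and Cldn8 2.89-fold (adjusted p = 5.77e-07, and adjusted p = 0.0618 with an estimated correlation). Basement membrane genes rose for 9 of 21 and fell for 3 (11 and 4 adjusted over the list alone), with Col4a4 up 9.26-fold (adjusted p = 0.00169, and adjusted p = 0.149 with an estimated correlation). Cholesterol synthesis genes rose for 8 of 17 and fell for 0 (10 and 0 adjusted over the list alone), with Hmgcs1 up 2.07-fold (adjusted p = 0.000752, and adjusted p = 0.242 with an estimated correlation). Immediate early genes rose for 6 of 22 and fell for 2 (8 and 2 adjusted over the list alone), with Fos up 2.71-fold (adjusted p = 0.000899, and adjusted p = 0.197 with an estimated correlation). Antigen presentation genes rose for 7 of 20 and fell for 0, Bst2 by 2.88-fold (adjusted p = 0.00523, and adjusted p = 0.0675 with an estimated correlation). FGF genes rose for 7 of 23 and fell for 1, with Fgf7 up 2.25-fold (adjusted p = 0.0284, adjusted p = 0.168 with an estimated correlation, and adjusted p = 0.17 by the probe sets with the highest mean). Cell cycle genes rose for 4 of 29 and fell for 0 (3 and 0 adjusted over the list alone), Prc1 by 1.59-fold (adjusted p = 0.0112, and adjusted p = 0.389 with an estimated correlation).

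Retinoid genes fell as a list in the epididymis, with 6 of 16 lower and 2 higher (9 and 2 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.0675 with an estimated correlation). Crabp1 fell 5.24-fold and Rarb, a retinoic acid receptor, 2.92-fold, while Aldh1a1 and Rbp4 (6.39-fold), the plasma carrier of retinol, rose. WNT genes fell for 9 of 35 and rose for 3 (10 and 4 adjusted over the list alone), Wnt4 by 5.36-fold and Wnt7a by 3.85-fold (adjusted p = 0.0209, and adjusted p = 0.097 with an estimated correlation). Erythroid markers fell for 5 of 13 and rose for 0 (adjusted p = 4.63e-06, and adjusted p = 0.02 with an estimated correlation). In all 2998 genes passed, 1764 up and 1234 down (637 and 205 at 2-fold or more). Without the E14.5 array of replicate 2, whose 5' minus 3' difference of added control RNAs was -1.02, the count was 1755, and without that of replicate 1 it was 4617. It was 2852 without the late vas deferens arrays and 3804 without the early efferent duct arrays. Quantile normalization gave 4841, and only the arrays of the groups compared gave far fewer, as stated below.

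In the vas deferens Aldh1a1 rose 38.2-fold from E14.5 to P1 (log2 5.26 ± 0.26 SE, 2 arrays per age, adjusted p = 2.33e-11), Aspn 37.5-fold (log2 5.23 ± 0.38) and Adgrg2, an adhesion receptor of duct epithelium, 32.7-fold (log2 5.03 ± 0.14). Hbb-y fell 750-fold (log2 -9.55 ± 0.38), Hba-x 41.7-fold and Hmga2 22.7-fold (log2 -4.50 ± 0.26). After quantile normalization these changes were smaller. Aldh1a1 was then at 3.77 (log2), Aspn at 3.82, Adgrg2 at 3.56, Hbb-y at -6.12 and Hba-x at -4.38, and Hmga2 also fell less. Nt5e, an ectonucleotidase (32-fold), Itih5 (27.0-fold), Maob (24.8-fold), Fst (21.0-fold), Thbs2, a matricellular protein (19.8-fold), Dclk1 (19.3-fold) and Ccn3 (17.5-fold) also rose. The rest of the falls were Rpl37a (36.6-fold), Atp5g2 (22.7-fold), Rps10 (22.2-fold), Gas5 (20.6-fold), Tmsb10 (19.8-fold), Atp5l (18.5-fold) and Uqcrh (17.7-fold). The P1 arrays here are late vas deferens arrays with low 5' signal, and other probe sets of these genes fell less or not at all, apart from Atp5l, which has no other. The probe set with the highest mean was at -0.11 for Rpl37a, 0.10 for Atp5g2, -0.03 for Rps10, -2.24 for Uqcrh, -0.17 for Gas5 and 0.21 for Tmsb10, and for Nt5e among the rises it was at 0.07. With centred ratios the highest mean favours probe sets that do not fall in a few arrays, so for the falls it is no independent check. Over all other probe sets of these genes the median was -1.38 for Rpl37a, -0.17 for Atp5g2, -1.77 for Rps10, -2.24 for Uqcrh, -0.61 for Gas5 and -0.13 for Tmsb10. The median of the other probe sets was 3.15 for Adgrg2, 2.98 for Itih5, 2.60 for Fst, 2.83 for Thbs2, 1.51 for Dclk1 and -2.80 for Hmga2.

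Matrix genes rose in the vas deferens for 16 of 24 and fell for 4 (16 and 5 adjusted over the list alone), with Col12a1 up 10.5-fold and Eln 8.76-fold (adjusted p = 3.35e-05, and adjusted p = 0.258 with an estimated correlation). Retinoid genes fell for 10 of 16 and rose for 3, with Crabp1 down 12.6-fold (adjusted p = 0.0477, adjusted p = 0.136 with an estimated correlation, and adjusted p = 0.066 without the early efferent duct arrays). Leaving out those arrays did not change the retinoid list median (-0.83, log2), since this change uses none of them. Imprinted growth genes fell for 8 of 18 and rose for 0 (9 and 0 adjusted over the list alone), with Nnat down 16.1-fold and Peg3 5.06-fold (adjusted p = 0.00621, and adjusted p = 0.197 with an estimated correlation). Anterior HOX genes fell for 12 of 19 and rose for 1, Hoxa5 by 2.41-fold (adjusted p = 0.0212, and adjusted p = 0.377 with an estimated correlation). Erythroid markers fell for 5 of 13 and rose for 0 (adjusted p = 0.011, and adjusted p = 0.097 with an estimated correlation). In all 7614 genes passed, 3446 up and 4168 down (1050 and 1929 at 2-fold or more), and the comparison has no value without the late vas deferens arrays. Over the 192 tests of lists, 65 were called, and 13 of these held with an estimated correlation. The median, the mean and the test differed in sign in 30 tests, of which 0 were called.

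Between successive ages, averaged over the 3 tissues, the interval from E16.5 to E18.5 held the most genes on all arrays, but not without both sets of arrays. From E14.5 to E16.5 Lcn2 rose 11.4-fold (log2 3.51 ± 0.21 SE, 6 arrays per age, adjusted p = 2.16e-09), Aspn 9.52-fold, Aldh1a1 8.54-fold, Dpt 7.60-fold and Aldh1a7 6.47-fold. Hbb-y fell 45.6-fold, Hba-x 10.2-fold, Hmga2 4.72-fold, Hbb-bh1 3.59-fold and Ecm1 3.46-fold. After quantile normalization Hbb-y was at -2.58 (log2) against -5.51, Aspn at 1.92 against 3.25 and Aldh1a1 at 1.67 against 3.09. The changes of Lcn2 (2.81), Dpt (2.22), Hba-x (-2.95), Hmga2 (-2.08) and Aldh1a7 were also smaller. Those of Hbb-bh1 (-1.98) and Ecm1 (-1.99) were slightly larger. In this interval 4106 genes passed, 2131 up and 1975 down, against 5565 without the early efferent duct arrays (2672 up and 2893 down) and 5753 without both sets, the latter averaged over epididymis and vas deferens. From E16.5 to E18.5 Nt5e rose 5.17-fold, Maob 4.04-fold, Fst 3.99-fold, C1qtnf3 3.64-fold and Fndc1 3.58-fold, and Hbb-y fell 10.4-fold, Crabp1 4.33-fold, Rpl37a 3.16-fold, Eif4a1, a translation factor, 3.10-fold, and Uqcrh 2.95-fold. With the late vas deferens arrays left out, Fst was at 0.70 (log2, adjusted p = 0.015), Rpl37a at -0.02, Eif4a1 at -0.44 and Uqcrh at -0.08, and without both sets Fst was at 0.42 (adjusted p = 0.26). The probe set of Nt5e with the highest mean was at -0.25, that of Rpl37a at 0.00 and that of Eif4a1 at -0.20, and the other probe set of Fndc1 was at -0.16. The count was 6850, with 3716 up and 3134 down. Without the late vas deferens arrays it was 4613, over efferent duct and epididymis, and without both sets 2245, for the epididymis alone. The balance turned without both sets, with 1008 up and 1237 down, and without the early efferent duct arrays, with 2810 up and 3176 down (116 and 504 at 2-fold or more).

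From E18.5 to P1, the interval that holds birth, 597 genes passed, 369 up and 228 down. Angptl4, a lipase inhibitor, rose 3.53-fold (log2 1.82 ± 0.11 SE, 6 arrays per age, adjusted p = 2.77e-08), Cirbp, a cold-inducible RNA binding protein, 2.84-fold, Ccn3 2.19-fold, Dner 2.14-fold and Trp63, a basal cell factor, 2.11-fold. Slc2a1, a glucose transporter, fell 2.49-fold (log2 -1.31 ± 0.08, adjusted p = 2.77e-08), Slc16a3, a lactate exporter, 2.11-fold, Ankrd37, a gene induced by low oxygen, 2.66-fold, Ak4, a mitochondrial adenylate kinase, 2.21-fold, and Fam199x 2.27-fold. Trp63 was at 0.09 (log2) without the late vas deferens arrays. The other probe sets of Fam199x had a median of 0.03, and the probe set of Ak4 with the highest mean was at -0.03. The other probe sets of Angptl4 and Trp63 were at 0.15 and 0.05. The count was 268 without the late vas deferens arrays and 1011 without the early efferent duct arrays. Leaving out 1 array gave 356 to 801, the former without the E18.5 epididymis array of replicate 1.

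Whether the time course differs between tissues was tested by the interaction of age and tissue, which 10861 genes passed. The change from E14.5 to P1 differed between efferent duct and epididymis for 4174 genes, between epididymis and vas deferens for 5750, and between efferent duct and vas deferens for 8730. Lrp2 rose by 2.32 (log2) more in the efferent duct than in the epididymis (adjusted p = 9.17e-06), and Actg2 changed by -4.09 in the same comparison (adjusted p = 3.57e-06). Lhx1, a transcription factor of early duct formation, rose in the efferent duct and fell by 1.91 in the vas deferens, a difference of 5.22. Fst rose by 4.39 in the vas deferens, and its change differed from that in the epididymis by -5.02. Sall1 fell by 3.09 in the vas deferens and rose by 1.01 in the efferent duct, a difference of 4.09. The differences for Lhx1, Fst and Sall1 use late vas deferens arrays at P1. Those for Lrp2, Actg2, Lhx1 and Sall1 use early efferent duct arrays at E14.5. None of these differences has a value without the arrays it uses. The 10 genes with the smallest interaction p were Gas5, Ndufa7, Uqcrh, Ly6e, Rpl37a, Cox6b2, Pfdn5, Sf3b5, Fau and S100a10. Each had its largest change in the vas deferens, from -2.15 for Ly6e to -5.19 for Rpl37a, where the P1 arrays are late vas deferens arrays. By the probe set with the highest mean, the change in epididymis against vas deferens was -0.13 for Pfdn5, -0.46 for Sf3b5 and -0.56 for S100a10, against 3.42, 3.29 and 3.91 by the main probe sets. It was 0.07 for Rpl37a, 0.23 for Gas5 and 0.45 for Ly6e, each with its call lost, and 2.22 for Uqcrh, 2.30 for Ndufa7, 2.79 for Cox6b2 and 2.88 for Fau, each with its call kept. The choice by the highest mean favours probe sets that do not fall in a few arrays, so the lost calls are no independent check.

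Across genes, the change from E14.5 to P1 correlated with r = 0.578 between efferent duct and epididymis, 0.271 between epididymis and vas deferens, and 0.103 between efferent duct and vas deferens. Genes are not independent replicates, so no p-value is given. In all 3 tissues 744 genes rose, 199 of them at least 2-fold, and 195 fell, 33 of them at least 2-fold. Lcn2, Dpt, Aspn and Aldh1a1 were among those that rose, and Hbb-y, Hba-x and Hmga2 among those that fell. Efferent duct and epididymis shared 1446 rising genes where independence would give 533.9, and 401 falling genes against 232.9. Epididymis and vas deferens shared 875 against 334.1 and 570 against 282.7, and efferent duct and vas deferens 1786 against 1042.9 and 350 against 786.7. The 3 changes share no arrays, but all take their residual spread from the same fit. The change in the efferent duct uses early efferent duct arrays at E14.5, and that in the vas deferens uses late vas deferens arrays at P1. Technical differences of these arrays cannot be told apart here from time courses that differ between tissues.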

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

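The exchange of whole groups and the test of the tissue RNA alone were chosen only after the result was seen, the latter in place of earlier tests of the opposite probe sets and of the highest single array, whose values are also given.

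The change from E14.5 to P1 differed between tissues by a test of the difference itself for 4174 genes (efferent duct against epididymis), 5750 (epididymis against vas deferens) and 8730 (efferent duct against vas deferens). Among the genes with the smallest interaction p, the change in the epididymis minus that in the vas deferens was 4.20 for Gas5, 4.0 for Ndufa7, 4.17 for Uqcrh, 3.30 for Ly6e, 5.22 for Rpl37a, 2.79 for Cox6b2, 3.42 for Pfdn5, 3.29 for Sf3b5, 2.88 for Fau and 3.91 for S100a10 (log2). The median of the other probe sets, where a gene has any, was smaller for each of them, as given above. In control probe sets outside the gene tests, the 5' minus 3' difference of the added control RNAs was lower in the 4 late vas deferens arrays than in the other 20, by a difference of -1.44. The hybridisation controls were lower in the 4 early efferent duct arrays, by a difference of -0.92.

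The late vas deferens arrays stood apart in their control RNAs, and the genes above changed most in them. A difference of the tissue RNA alone, such as a biological loss of these transcripts or degraded tissue RNA, is argued against by the added control RNAs, whose mean index was -1.27 (SD 0.13) in the 4 arrays and 0.17 (SD 0.35) in the other 20, a difference of -1.44. The gap is small: the highest of the 4 was at -1.16, the lowest of the 20, epididymis E14.5 replicate 2, at -1.02. The index differed by more for the tissue transcripts Gapdh (-2.85) and Actb (-2.06). In epididymis E14.5 replicate 2 Gapdh was only at -0.54 and Actb at -0.81, against -2.94 to -2.68 and -2.36 to -1.78 in the 4 arrays. A part from the tissue RNA beside the labelling, degraded RNA included, is therefore not excluded. Labelling that reaches less far from the 3' end may account for part of the pattern: across genes, the replicate difference in the epididymis at E14.5, where replicate 2 has the low index, correlated with the late vas deferens difference at r = 0.36, against 0.24 at most for the replicate differences of other groups, and genes are not independent replicates. Of 480 genes with several called probe sets in P1 against E14.5 in the vas deferens, 54 (11.2%) had probe sets moving in opposite directions, against 21 of 417 (5.0%) in the efferent duct and 0 of 213 in the epididymis, and a real change of the vas deferens with age stays open, untested apart from the labelling, since all arrays of these ages share the low index.

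In the early efferent duct arrays the wide spread of log2 ratios and the low hybridisation controls went together. If weaker hybridisation were the cause, the replicate difference of each early age, of which replicate 2 has the lower controls, was predicted to follow the early efferent duct difference of the other age at r over 0.2 across genes, and if not, both r would be under 0.1. They were 0.05 and 0.22, which decides neither way, and genes are not independent replicates. Weaker hybridisation and a real difference of the efferent duct at E14.5 and E16.5 therefore cannot be told apart for these arrays, since no other array of that tissue has these ages.

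Other splits of the arrays within age or tissue were counted for the main results, 100 for each with the real split included, and in each case 1 split, the real one, gave a result as large. Most such splits part the replicates of a group and so widen the residual spread, so they exclude only that single arrays fell into these groups by chance. The real and the highest other counts were 10386 and 8342 for efferent duct against epididymis, 8089 and 7354 for epididymis against vas deferens, and 12644 and 9310 for efferent duct against vas deferens. They were 4106 and 4078 for E14.5 to E16.5, 6850 and 5830 for E16.5 to E18.5, and 597 and 69 for E18.5 to P1. For enriched genes they were 204 and 64 in the efferent duct, 33 and 1 in the epididymis, and 157 and 0 in the vas deferens, and for lists called between tissues 37 and 35. The high counts of other splits point to a structure of the samples: the highest split kept the 2 arrays of every group together and exchanged whole groups, at 4 of 4 ages for each tissue comparison and in 3 of 3 tissues for the earlier intervals.

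With whole groups exchanged the residual spread stays the same. The tissue comparisons then have 8 splits and the intervals 4, too few for a share under 0.05, and the real counts above were the highest, with the highest other at 8731, 7797 and 10519 for the tissues and 4078, 5830 and 29 for the intervals. Of 100 such splits, the real one included, 4 gave as many genes enriched in the efferent duct, 26 in the epididymis and 6 in the vas deferens, with the highest other at 296, 172 and 291, and 10 gave as many lists between tissues, with the highest other at 43. With whole groups as units, chance is therefore not excluded for the numbers of genes enriched in the epididymis or the vas deferens or for the number of lists. Nor is it excluded for the counts of the tissue comparisons and the intervals, which have too few splits. The splits do not tell technical from biological differences.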

How the results depend on the processing

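The fits without the late vas deferens arrays, without the early efferent duct arrays and without both, the probe set with the highest mean, the probe set by variance over 20 arrays and the genes above the median variance were chosen after the results were seen. The stricter of the percentile filters planned was not run, since centred ratios hold no levels, and for the same reason signal over background cannot be read. The probe set with the highest mean is likewise not the one with the highest level, and this choice favours probe sets that do not fall in a few arrays. Leaving out 1 array leaves a group with a lone array that is assumed to vary like the other groups. A count is treated as kept when it is within 1.5 times the main one. Of 22 main results, all 22 were kept under array median centring, under moderation with trend and robust, under the probe set with the highest mean, under the probe set by variance over 20 arrays and with a replicate block. The counts split by direction or at 2-fold moved more: of 51, 14 were lower by over 1.5 times under the probe set with the highest mean and 23 under the mean of all probe sets. With that block WNT signalling (-0.17) and epithelial adhesion (0.15) in efferent duct against epididymis, and Fam199x (-1.18) in P1 against E18.5, lost their calls, each at adjusted p = 0.051. The direction that held more genes changed in efferent duct against epididymis under quantile normalization, array median centring and the probe set with the highest mean, in E18.5 against E16.5 under quantile normalization, in E16.5 against E14.5 under the mean of all probe sets and the probe set with the highest mean, and in epididymis against vas deferens and in P1 against E14.5 in the vas deferens under the probe set with the highest mean. The cause of the changes below was not tested, except that fewer genes or fewer arrays were tested where the setting says so.

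Quantile normalization gave 5785 genes for P1 against E14.5 in the efferent duct, 4841 in the epididymis, 59 genes enriched in the epididymis, and r = 0.41 (epididymis and vas deferens) and 0.17 (efferent duct and vas deferens) for the age changes across genes. The mean of all probe sets gave 21 genes enriched in the epididymis, 70 in the vas deferens and r = 0.43 for epididymis and vas deferens. Array weights gave 1324 genes for P1 against E18.5. An estimated correlation left 10 list calls between tissues and 3 between ages, and fry gave 72 and 56. Only the arrays of the groups compared gave 5634 genes for P1 against E14.5 in the efferent duct, 830 in the epididymis, 2711 for E16.5 against E14.5, 1032 for P1 against E18.5 and 3825 for the tissues at E14.5. Without the late vas deferens arrays there were 1050 genes for epididymis against vas deferens, 268 for P1 against E18.5 and 64 enriched in the vas deferens. Without the early efferent duct arrays there were 3995 for efferent duct against epididymis, 1011 for P1 against E18.5, 322 enriched in the efferent duct and 16 list calls between ages, against 17 on all arrays for the comparisons that this fit has. Without both there were 4104 for efferent duct against epididymis, 1334 for epididymis against vas deferens, 2245 for E18.5 against E16.5, and 23 and 13 list calls, against 26 and 12 on all arrays for the comparisons left. The genes above the median variance gave 6278 for efferent duct against epididymis, 8071 for efferent duct against vas deferens, 5375 for P1 against E14.5 in the efferent duct, 5596 and 6412 for the tissues at E14.5 and E16.5, 23 list calls between tissues and r = 0.16 for efferent duct and vas deferens.

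Leaving out each of the 24 arrays gave ranges of 9401 to 10807 (efferent duct against epididymis), 7553 to 8391 (epididymis against vas deferens), 11874 to 12887 (efferent duct against vas deferens), 6425 to 9532 (P1 against E14.5, efferent duct), 1755 to 4617 (epididymis, without E14.5 replicate 2 and replicate 1) and 6140 to 7936 (vas deferens). The intervals ranged over 3171 to 4906, 5586 to 7425 and 356 to 801, the tissues at each age over 7304 to 10068, 7684 to 10779, 7345 to 9034 and 8004 to 9396, and the interaction over 9927 to 11640. Enriched genes ranged over 199 to 221, 31 to 40 and 144 to 168, list calls over 33 to 39 and 24 to 29, and r over 0.52 to 0.59, 0.16 to 0.37 (without epididymis E14.5 replicate 1 and replicate 2) and 0.06 to 0.14.

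These values changed sign. Under quantile normalization Ly6e had -0.01 for the change in efferent duct against epididymis. The median of the epithelial adhesion list was -0.02 in epididymis against vas deferens and -0.09 in efferent duct against vas deferens without the late vas deferens arrays, and -0.02 in the former without both sets. The probe set with the highest mean gave Hoxa10 0.08 (efferent duct against epididymis), Lrrc17 -0.07 (epididymis against vas deferens), Atp5g2 0.10 and Tmsb10 0.21 (P1 against E14.5, vas deferens), Nt5e -0.25 and Rpl37a 0.00 (E18.5 against E16.5), and for the change in epididymis against vas deferens Pfdn5 -0.13, Sf3b5 -0.46 and S100a10 -0.56, with S100a10 -0.58 for efferent duct against vas deferens. The probe set by variance over 20 arrays gave S100a10 -0.21 (epididymis against vas deferens) and changes of -1.45 (epididymis against vas deferens) and -1.49 (efferent duct against vas deferens), and Sf3b5 -0.46 (the former). The median of the other probe sets gave Hoxa10 0.08, Irs4 0.08 and Foxl2 0.07 (efferent duct against epididymis), S100a10 -0.06 and Lrrc17 -0.07 (epididymis against vas deferens), Fndc1 -0.05, Top3b 0.23, Ddx5 0.29 and Aldh2 0.10 (P1 against E14.5, efferent duct), Fndc1 -0.16 (E18.5 against E16.5), Fam199x 0.03 (P1 against E18.5) and changes of S100a10 of -1.0 (epididymis against vas deferens) and -1.03 (efferent duct against vas deferens).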

Other observations

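The list of oxygen-regulated genes was chosen only after the fall of Slc2a1, Slc16a3, Ankrd37 and Ak4 was seen, and before the values of its members were seen.

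Genes that cells induce at low oxygen, many of them enzymes of glycolysis, fell from E18.5 to P1 over the 3 tissues. Of 30 listed genes 27 were measured, with Slc2a1, Slc16a3, Ankrd37, Ak4 and Angptl4 left out, and 17 fell, 0 rose and 10 did not pass the test over all genes (22 fell and 1 rose adjusted over the list alone, 6 arrays per age). Egln3, a prolyl hydroxylase that senses oxygen, fell by 1.05 (log2, SE 0.09, adjusted p = 2.21e-06), and Pfkl, a phosphofructokinase, by 1.04 (SE 0.09). Ldha, lactate dehydrogenase, fell by 0.96 (SE 0.08), Vegfa, an angiogenic factor, by 0.91 (SE 0.08), Bnip3, a mitochondrial receptor for autophagy, by 0.87 (SE 0.07), and Pdk1, which limits pyruvate oxidation, by 0.80 (SE 0.11). Adm was at 0.33 (adjusted p = 0.107), and Angptl4, which is also induced by fasting and lipids, rose.

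A hypothesis is that the oxygen-regulated programme of transcription may be less active in these tissues after birth. It predicted a median below 0 for the other oxygen-regulated genes, which was -0.57 (log2), with 25 of 27 below 0, and camera gave p = 3.15e-41, and p = 6.65e-07 with an estimated correlation. Without the late vas deferens arrays the median was -0.54 and p = 1.92e-06 with an estimated correlation. Whether the time between death and freezing of the tissue differed between E18.5 and P1 is not given in the labels, and such a difference stays open beside birth itself.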
